A study of Acipenser ruthenus with 15 samples.

How the data were processed

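The samples are eggs of the sterlet, Acipenser ruthenus, a small sturgeon, which the labels call oocytes of stage 1. Per the labels' protocols, each egg was embedded in a freezing medium, sliced on a cryostat and divided into 5 segments named A to E from the animal pole, the side of an egg that holds the nucleus, to the vegetal pole, the yolk-rich side. There were 3 eggs, numbered 10, 18 and 20, and 1 library per segment of each egg, 15 libraries in all. RNA was extracted with TRIzol, precipitated again with lithium chloride, depleted of ribosomal RNA with Ribo-Zero and made into strand-specific libraries with the SureSelect kit for Illumina sequencing, per the labels' protocols. The relation of the eggs to females is not given in the sources used here, so the p-values of the section comparisons cover these 3 eggs only. They measure how evenly section differences repeat over the eggs, after each egg's own level is removed, with the spread pooled over all sections.

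The authors deposited 2 files per library. One holds whole-number counts per assembled transcript, the deposited counts, with no header. The other holds the deposited normalized signal, which equals the deposited counts divided by 1 number per library, with a relative range of that ratio of at most 9.8e-10 over transcripts with more than 50 counts. That number is called the deposited factor here. The submitters' processing notes name Trimmomatic, STAR 2.5.2b, kallisto and DESeq2 without saying what each was used for, and the assembly that the reads were assigned to is not given in the sources used here. The counts were used for every test, and the deposited signal only to obtain the deposited factor.

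Each file lists 42878 transcripts by an assembly ID, 28041 with a DN number and 14837 with a GG number, the forms that the Trinity assembler gives to de novo and genome-guided assemblies. The ID also holds the component, the gene and the transcript number. The files do not pair the IDs with gene names, and 0 of them matched the table of annotated sterlet genes used here. No gene name is therefore given. The gene lists fixed in advance, for germ plasm, vegetal determinants and other groups, could not be applied, so no set test was run on them, and no transcript could be removed as mitochondrial or ribosomal. Position in the genome, GC content, length and markers of other cell types were not analysed here. One further line of each count file, the spike-in, is no transcript. It held 0.0115 to 0.0235% of the counts and stayed out of library sizes and tests.

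Library totals ran from 4347026 to 14500611 counts. Transcripts were kept by filterByExpr in edgeR, which left 29102 for testing, with 99.6% of the counts of every library, while 575 had no count in any library. Libraries were scaled with TMM. The test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The model had the section and the egg as additive terms over all 15 libraries, with 8 residual degrees of freedom, and a common biological coefficient of variation of 0.123. The egg was kept as a block because the 5 segments are regions of the same egg. As a check of that pairing, deviations from the section means were correlated between libraries. The correlation was 0.274 to 0.726 for libraries of the same egg and -0.752 to 0.3 for libraries of different eggs. Counts of libraries of the same section differed by 4.77 to 27.2 in chi-square per degree of freedom over transcripts with at least 20 counts in the pair, so no 2 libraries of a section agree within sampling noise.

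The comparisons, fixed before the data were examined, were an F test of any difference between sections, section E against section A, and each pair of adjacent sections. Each transcript past the F test was also placed in the section with its highest mean CPM. The rule for the transcripts named in the text was fixed at the same time. It takes those with the largest fold change per direction among those past the threshold with the same direction in 3 of 3 eggs and a mean of at least 5 CPM, those with the largest ratio of section B, C or D to the mean of the other sections, and the most abundant. As no gene names were matched, at most 2 transcripts per direction are named. Fold changes are ratios of TMM-scaled CPM or log2 values from edgeR. A fold against a section with 0 counts is a lower bound computed with 3 counts per library, and ratios over 1 to 3 counts carry an exact 95% Poisson interval. The intervals come from the low count summed over the 3 eggs, and neither they nor the bounds cover the spread between eggs. Both cover counting error only, and may fall short of it, since the reads carry no molecular identifiers. Directions within eggs and medians over transcript sets used log2 of CPM plus 0.5.

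The test was tested on simulated data drawn from the means and library sizes of these libraries. As many transcripts were set to rise as to fall, along an even gradient from A to E. The simulation therefore does not test the choice of scaling. With 200 changed transcripts, the comparison of sections E and A recovered 30.6% of those changed 1.5-fold, 65.3% at 2-fold, 89.8% at 4-fold and 100% at 8-fold, and 6.62% of its 151 calls were false. In the same simulation, 14.9% of the 148 calls of the F test were false. With 9000 changed transcripts the false share was 3.33% for sections E and A and 3.43% for the F test.

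Alternatives fixed before the data were examined were DESeq2 size factors in the edgeR test, total counts only, the DESeq2 test, no low-count filter, a CPM filter, no replicate block, sections A and E alone, a fold threshold, and leaving out each egg and each library in turn. Further alternatives were chosen after seeing the data. These were the deposited factor and the spike-in as scaling, a robust variance estimate, sums per Trinity gene or component, removal of the 10 or the 2 most abundant transcripts, and other scalings for the medians over transcript sets. The software was edgeR 4.0.16 and DESeq2 1.42.0 under R 4.3.3, and matplotlib 3.10.9 under Python 3.11.15.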

Results

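RNA was measured along the animal-vegetal axis of sterlet eggs, to find transcripts whose level differs between positions. Each of 3 eggs gave 5 segments, from section A at the animal pole to section E at the vegetal pole, and 1 library per segment, so n = 3 in each section. The shallowest library, section C of egg 20, held 4347026 counts and the deepest, section D of egg 18, held 14500611. Levels are TMM-scaled CPM, counts brought to a common library size, given as mean ± SD over the 3 eggs. They state a transcript's level relative to the other transcripts of its library, not an amount per section.

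The vegetal and the animal pole held different RNA. trinitytrinLocDN53737c0g1t2 stood at 32.1 ± 14.8 CPM (SD, n = 3) in section E and had 0 counts in section A, which makes it at least 101-fold higher at the vegetal pole. trinitytrinLocGG_92422c0g1t1 stood at 24.6 ± 8.74 CPM in section E, again with 0 counts in section A, and was at least 77.6-fold higher. At the animal pole, trinitytrinLocGG_86527c0g1t1 had 974 counts in section A and 0 in section E, at least 95.2-fold higher in A. trinitytrinLocDN53171c2g2t1 was 164-fold higher in A than in E, with 1796 counts against 14, of which 13 were in egg 20. Its log2 change was -6.95 over all libraries, -9.59 without section E of egg 20, -9.64 without egg 20 and -6.34 without egg 18.

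In all, 10222 of 29102 transcripts differed between sections E and A, 5090 of them higher in E and 5132 higher in A (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). For 9940 of these the direction was the same in 3 of 3 eggs. At least 2-fold changes were found for 2396 transcripts higher in E and 2095 higher in A. At least 4-fold changes were found for 1156 and 533, and at least 16-fold changes for 327 and 72. The adjusted p from edgeR with Benjamini-Hochberg adjustment was 1.68e-10 for trinitytrinLocDN53737c0g1t2, 1.14e-08 for trinitytrinLocGG_92422c0g1t1, 9.86e-09 for trinitytrinLocGG_86527c0g1t1 and 1.65e-10 for trinitytrinLocDN53171c2g2t1. The 2 most abundant transcripts were higher in E as well, trinitytrinLocGG_75266c0g1t1 by a log2 change of 1.17 ± 0.14 (SE) and trinitytrinLocGG_45939c0g1t1 by 1.40 ± 0.14 (SE). Without gene names, ribosomal or mitochondrial origin of these 2 could not be checked.

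The balance of directions between sections E and A depended on the scaling. With TMM, 49.8% of the called transcripts were higher in E, against 39.6% with total counts only, 15.8% with the spike-in as scaling and 11.9% with the deposited factor. The median log2 change of all transcripts was -0.61 with the deposited factor, -0.53 with the spike-in and -0.11 with total counts only, against -0.02 with TMM. Under the deposited factor, 359 of the 7655 transcripts called both ways had the opposite direction, and at least 4-fold changes numbered 800 higher in E and 1257 higher in A, while at least 16-fold changes numbered 228 and 134. Every transcript named for sections E and A kept its direction and its call under these scalings. The deposited factor and the spike-in each move all transcripts of a library by 1 amount, whose uncertainty the tests leave out.

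**Figure D1:**
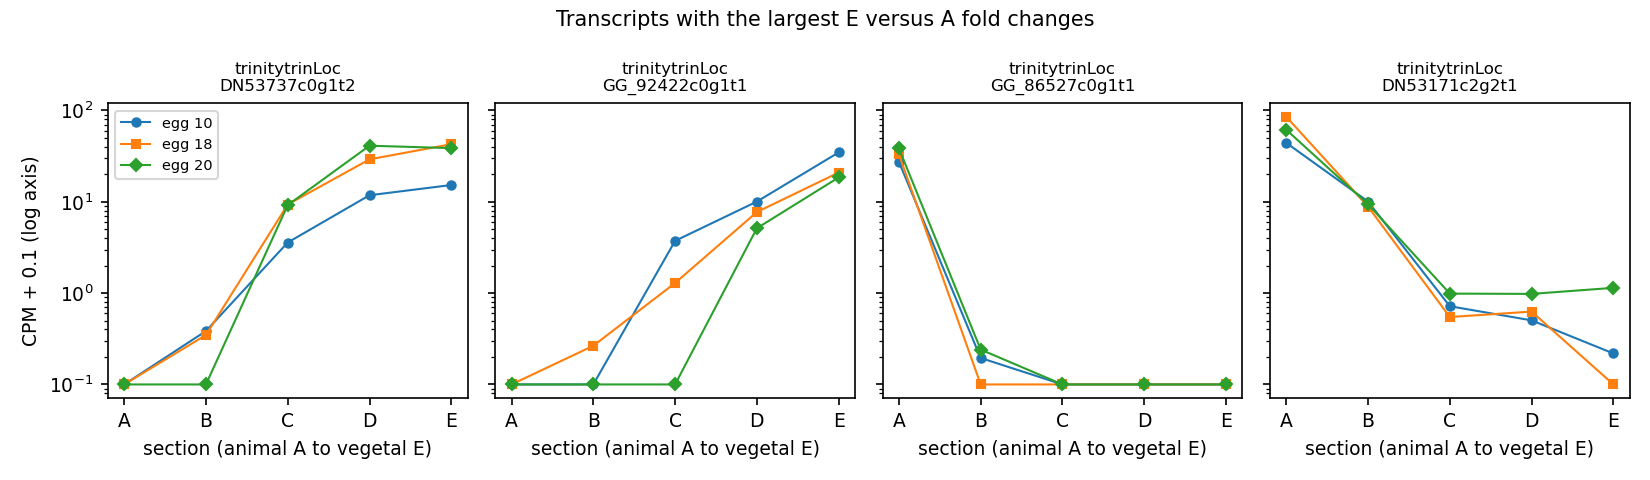
Level of the 4 transcripts named for sections E and A in each of the 15 libraries, in CPM with a small offset on a log axis, against section from A (animal) to E (vegetal), with 1 line per egg. The first pair has 0 counts in section A and is higher in sections D and E in each egg, and the second pair is highest in section A in each egg.

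The share of a section's counts held by the transcripts that differed between poles changed along the axis. The 2396 transcripts at least 2-fold higher in E made up 5.87 ± 0.372% of the counts in section A and 6.16 ± 0.397% in section B, then 11.8 ± 1.54% in C, 15.8 ± 0.804% in D and 18.4 ± 1.19% in E (SD, n = 3). The 2 most abundant transcripts, trinitytrinLocGG_75266c0g1t1 and trinitytrinLocGG_45939c0g1t1, belong to this set and alone took 2.97 ± 0.297% of the counts in A, 2.60 ± 0.434% in B, 4.97 ± 1.11% in C, 6.09 ± 1.25% in D and 6.76 ± 0.851% in E. The 2095 transcripts at least 2-fold higher in A made up 11.7 ± 0.859% of the counts in section A, 8.13 ± 0.892% in B, 5.53 ± 1.05% in C, 4.18 ± 0.737% in D and 3.63 ± 0.556% in E. The median log2 change of the vegetal set was 0.22 ± 0.01 from A to B and 0.75 ± 0.16 from B to C. For the animal set these medians were -0.46 ± 0.13 and -0.48 ± 0.11. How far the medians of these steps lay apart depended on the scaling: with the deposited factor the medians were 0.47 ± 0.02 and 0.59 ± 0.16 for the vegetal set and -0.20 ± 0.13 and -0.69 ± 0.11 for the animal set. With the spike-in they were 0.41 ± 0.31 and 0.50 ± 0.24 for the vegetal set and -0.28 ± 0.38 and -0.79 ± 0.12 for the animal set. From C to D and from D to E the vegetal medians were 0.50 ± 0.11 and 0.27 ± 0.04 with TMM. They were 0.14 ± 0.13 and 0.02 ± 0.03 with the deposited factor, and -0.08 ± 0.26 and 0.47 ± 0.15 with the spike-in. For the animal set they were -0.27 ± 0.13 and -0.19 ± 0.12 with TMM. The deposited factor gave -0.61 ± 0.13 and -0.41 ± 0.10, and the spike-in -0.82 ± 0.16 and 0.01 ± 0.215. Both sets were chosen on these libraries, so the difference between sections E and A is built into them, and with 3 eggs an exact paired test of 2 steps cannot go below p = 0.25.

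**Figure D2:**
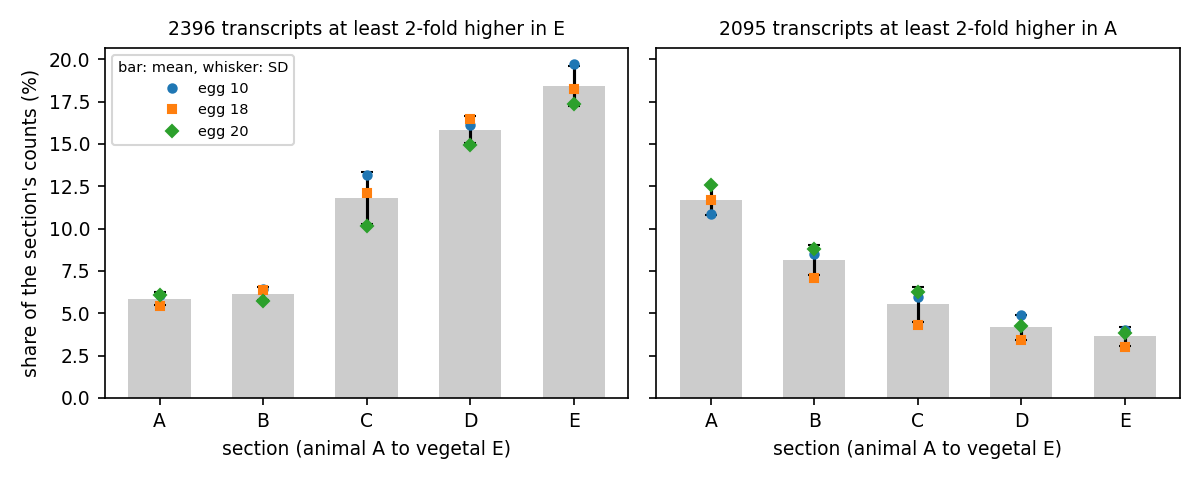
Share of each section's counts, in percent, taken by the 2396 transcripts at least 2-fold higher in section E (left) and the 2095 at least 2-fold higher in section A (right), with bars for the mean of 3 eggs, whiskers for the SD and 1 point per egg. The vegetal set goes from 6.16% in section B to 11.8% in section C, and the animal set from 11.7% in section A to 8.13% in section B.

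Sections A and B differed mainly by transcripts higher at the animal pole. trinitytrinLocGG_86527c0g1t1, confined to section A apart from 2 counts in section B and 0 counts in C, D and E, was 418-fold higher in A than in B (95% counting interval 116 to 3450). Its log2 change was -8.64, and -7.97 without section B of egg 18 and -7.96 without egg 18. trinitytrinLocDN50594c0g2t1 went the other way and was 11.5-fold higher in B, with 306 counts against 25. Its level of 10.3 ± 1.13 CPM in B was still far below the 117 ± 14.9 in C, 141 ± 21 in D and 122 ± 8.95 in E. In all, 986 transcripts differed, 772 higher in A and 214 higher in B, and all 986 had the same direction in 3 of 3 eggs. The adjusted p from edgeR with Benjamini-Hochberg adjustment was 5.31e-07 for trinitytrinLocGG_86527c0g1t1 and 1.48e-07 for trinitytrinLocDN50594c0g2t1, while DESeq2 with the same adjustment gave 0.444 for the former. The share higher in B was 21.7% with TMM, 30.4% with total counts only, 45.8% of 526 calls with the spike-in and 90.8% of 5789 calls with the deposited factor.

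Between sections B and C the direction was mainly toward the vegetal side. trinitytrinLocGG_5183c1g2t1 was 41.3-fold higher in C (95% counting interval 7.41 to 1630), with 49 counts against 1. Its log2 change was 5.37, and 7.12 without section B of egg 20, which held that count, 7.15 without egg 20 and 4.58 without egg 10. trinitytrinLocDN53171c2g2t1 was 14.3-fold higher in B, at 9.33 ± 0.599 CPM against 0.651 ± 0.222 (SD, n = 3). In all, 2531 transcripts differed, 1702 higher in C and 829 higher in B, with at least 2-fold changes for 880 and 180. The adjusted p from edgeR with Benjamini-Hochberg adjustment was 8.41e-05 for trinitytrinLocGG_5183c1g2t1 and 1.11e-05 for trinitytrinLocDN53171c2g2t1. The share higher in C was 67.2% with TMM, 51.7% with total counts only, 36.2% with the spike-in and 22.2% of 5151 calls with the deposited factor.

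With TMM, fewer transcripts differed between sections C and D. trinitytrinLocGG_62355c0g1t1 was 10.7-fold higher in D, at 10.5 ± 6.08 CPM against 0.979 ± 1.7 (SD, n = 3). All its 38 counts in section C were in egg 10, so the fold rests on that library: the log2 change was 3.48, and 8.91 without section C of egg 10, 9.29 without egg 10 and 4.70 without section D of egg 10. trinitytrinLocDN43380c0g1t2 was 7.66-fold higher in C, at 30.5 ± 18.7 CPM against 3.99 ± 1.76. In all, 732 transcripts differed, 585 higher in D and 147 higher in C. The adjusted p from edgeR with Benjamini-Hochberg adjustment was 0.0103 for trinitytrinLocGG_62355c0g1t1 and 7.63e-06 for trinitytrinLocDN43380c0g1t2. The former call ended without egg 20 (edgeR with Benjamini-Hochberg adjustment, 0.176), without section C of egg 20 (0.0603), with the robust variance estimate (0.186), with DESeq2 (0.257) and without the egg as a block (0.83), where trinitytrinLocDN43380c0g1t2 lost its call too (0.0724). The share higher in D was 79.9% with TMM, 67.6% with total counts only, 3.23% of 10195 calls with the deposited factor and 0.718% of 12542 calls with the spike-in.

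Sections D and E were the most alike of the adjacent pairs by number of calls with TMM. trinitytrinLocGG_5183c1g2t1 was 5.36-fold higher in E, at 46.5 ± 13.1 CPM against 8.68 ± 1.83 (SD, n = 3). trinitytrinLocDN48002c3g2t2 was 2.05-fold higher in D, at 22.2 ± 7.15 CPM against 10.9 ± 5.27. In all, 82 transcripts differed, 78 higher in E and 4 higher in D, while 2257 had an unadjusted p under 0.05. The number called was unstable: 9 to 218 on leaving out an egg or a library, 4 without the egg as a block and 252 with DESeq2. The adjusted p from edgeR with Benjamini-Hochberg adjustment was 1.27e-05 for trinitytrinLocGG_5183c1g2t1 and 0.0165 for trinitytrinLocDN48002c3g2t2, and the latter call ended without egg 18 (0.301), without egg 20 (0.24), without section D or E of egg 10 (0.107 and 0.0621) or of egg 18 (0.131 and 0.108), without section E of egg 20 (0.0849), with the spike-in (0.199) and without the egg as a block (1). The share higher in E was 95.1% with TMM, 94.2% with total counts only and 95.8% of 119 calls with the spike-in, against 2.01% of 3586 calls with the deposited factor.

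**Figure D3:**
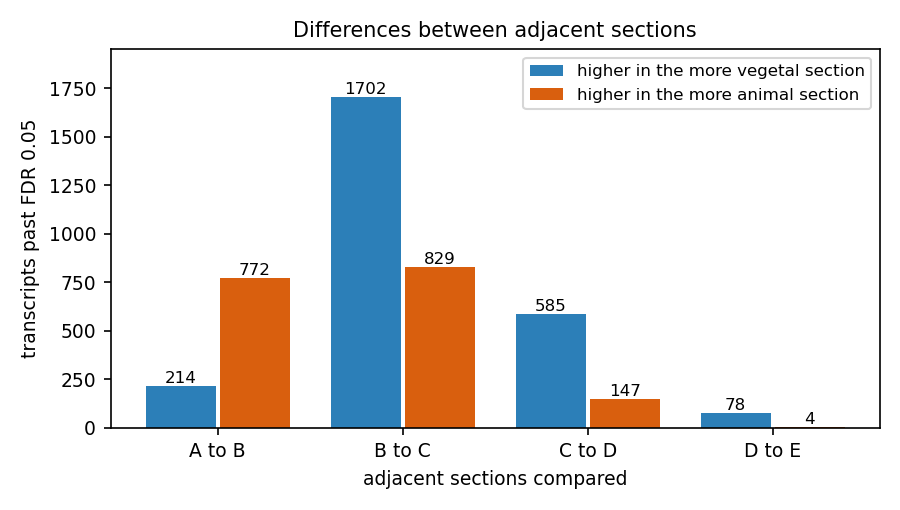
Number of transcripts that differed between adjacent sections, as bars for those higher in the more vegetal and in the more animal section of each pair (edgeR, TMM scaling). Sections A and B differ mainly by transcripts higher in A, 772 against 214, and sections B and C by transcripts higher in C, 1702 against 829. The balance of every pair shown reverses with the deposited factor. Those of B and C and of C and D also reverse with the spike-in.

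Over all sections, most transcripts that varied were highest at a pole. The F test called 9292 of 29102 transcripts (31.9%, edgeR with Benjamini-Hochberg adjustment), of which 3345 were highest in section A, 1089 in B, 453 in C, 981 in D and 3424 in E. The highest section was the same in 3 of 3 eggs for 1964 of the transcripts highest in A and 1851 of those highest in E, but for only 210, 119 and 160 of those highest in B, C and D. A transcript highest in A had a median of 28.7% of its summed level in section A and 14.5% in E, and one highest in E had 29.1% in E and 13.6% in A. With the deposited factor the F test called 21400 transcripts, and 14184 of them were highest in section B, against 2663 in A and 837 in E. With the spike-in it called 19457, of which 12946 were highest in B, 3929 in A and 1511 in E. Both scalings move all transcripts of a library by 1 amount, and the p-values leave out the uncertainty of that amount. The deposited factor over the TMM size varied by at most 0.801% within a section and was lowest in B, at 0.757. A lower factor raises every transcript there, so many of these calls and the peak in B can follow from the scaling alone.

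Single transcripts were highest in a middle section in each egg. trinitytrinLocDN46448c0g1t1 stood at 11.8 ± 4.86 CPM in section B (SD, n = 3), with section A nearest at 7.53 ± 2.81. It stood at 6.02 ± 2.15 CPM in C, 5.29 ± 1.34 in D and 4.24 ± 2.31 in E. Its level in B was 2.04 times the mean of the other sections. trinitytrinLocDN53053c0g1t2 stood at 748 ± 90.8 CPM in section C, 2.05 times that mean. Its level was 554 ± 41.7 CPM in D and 588 ± 74.2 in E, against 66.7 ± 4.78 in A and 253 ± 68.3 in B, so the ratio rests largely on A and B. trinitytrinLocDN63189c0g1t1 stood at 24.8 ± 4.3 CPM in section D, 2.81 times that mean, with 18.4 ± 2.4 CPM in section E. It stood at 1.12 ± 0.129 CPM in A, 2 ± 0.216 in B and 13.8 ± 3.73 in C. The adjusted p of the F test in edgeR with Benjamini-Hochberg adjustment was 0.000106, 5.03e-11 and 2.32e-11 for these transcripts in turn, and the first rose to 0.137 without the egg as a block. The F test asks whether any sections differ, so these values do not test for a peak in a middle section.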

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

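All tests in this part were chosen after the values were seen. Data outside the comparisons held a signal that went with section, in the deposited normalized signal and in the spike-in, a line of 693 to 3407 counts per library against a limit of 3 for a count of 0. The deposited factor, divided by the TMM-scaled library size, was 1.51 times as high in section E as in section A. Its mean was 0.927 in A, 0.757 in B, 0.881 in C, 1.16 in D and 1.40 in E. The spike-in stood at 232 ± 23.3 TMM-scaled CPM in section D (SD, n = 3), against 138 ± 24.7 in A, 119 ± 10.5 in B, 149 ± 15.6 in C and 200 ± 41.2 in E. Section D was above section A in 3 of 3 eggs, and the sections differed in a permutation test within eggs of any difference in level (p = 0.0011, 0.0045 after Benjamini-Hochberg adjustment over 4 measures).

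For the deposited factor, a factor that equalizes the spike-in of each library is argued against, since spike-in counts divided by it had a coefficient of variation of 17.3% over 15 libraries. Within a section the deposited factor was close to proportional to the TMM size. That its part beyond TMM size follows depth is argued against, since that part varied by at most 0.801% within a section while depth varied by 22.9 to 54.9%. The values fit a multiplier per section that the 3 eggs share, with 1.84 between the highest and the lowest section. A candidate explanation is that the authors scaled each section by an amount, such as its RNA, that was taken as equal in the 3 eggs. What the multiplier stands for, when the spike-in was added, and whether the sections of an egg hold different amounts of RNA stay open, and no biological explanation was tested.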

How the results depend on the processing

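DESeq2 size factors, both low-count filters and, among the alternatives chosen after seeing the data, Trinity gene and component sums, the robust variance estimate and removal of the most abundant transcripts kept the total of every comparison within 1.5 times, as did sections A and E alone for E versus A, the comparison run there. Of the values of named transcripts under alternatives, 457 kept direction and call and the other 17 kept direction but lost the call. None reversed.

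With the deposited factor, chosen after seeing the data, any section difference (F test) was called for 21400 transcripts, E versus A for 18145 (2164 higher in E, 15981 higher in A), B versus A for 5789, C versus B for 5151, D versus C for 10195 and E versus D for 3586. The section of highest level was B for 14184, C for 3038 and E for 837. With the spike-in, also chosen after seeing the data, the F test called 19457, E versus A 1955 higher in E and 10381 higher in A, B versus A 526 and D versus C 12542, and the highest level was in B for 12946, C for 1025, D for 46 and E for 1511. Each of these scalings moves all transcripts of a library by 1 amount, which the tests take as known. With the deposited factor that amount, relative to TMM, was nearly the same in the 3 eggs of a section. Many of these calls can therefore follow from the scaling alone. With total counts only, 2670 were highest in B. The DESeq2 test called 252 for E versus D, where 76 of the 82 remained; the cause was not tested. An absolute log2 change of at least 1 left 4491 for E versus A (2396 and 2095), and the same highest section in 3 of 3 eggs left 1964, 210, 119, 160 and 1851 for A to E, by construction.

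Without the replicate block, the pairing of the segments by egg is ignored and fewer transcripts were called: 4580 in the F test, 5925 for E versus A (3171 higher in E, 2754 higher in A), 391 for B versus A, 1020 for C versus B, 187 for D versus C and 4 for E versus D, each of them also called with the block.

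Leaving out an egg or a library gave 5663 to 10227 for the F test, 6913 to 10534 for E versus A (3592 to 5231 higher in E, 3305 to 5335 higher in A), 419 to 1385 for B versus A, 1286 to 3271 for C versus B, 158 to 1044 for D versus C and 9 to 218 for E versus D. Leaving out each egg, the highest level was in A for 2043 to 3307, B for 466 to 729, C for 141 to 345, D for 434 to 832 and E for 2376 to 2958. Counts moved over 1.5 times without egg 18 (F test 5865, higher in A 3305, B versus A 458, C versus B 1370, D versus C 276, E versus D 12) and egg 20 (5663 for the F test, then 419, 1286, 158 and 9), and without egg 10 for C versus B (1670) and E versus D (44). Numbers highest in A, B, C and D also moved that far without egg 18 (2043, 626, 251 and 537). Those highest in B, C and D did so without egg 20 (466, 141 and 434). Single libraries did so for B versus A (A18 653, B18 654, B20 638), C versus B (B10 1612, C10 1609), D versus C (D18 406, C20 338, D20 430) and E versus D (A10 218, D10 13, E10 30, B18 53, D18 17, E18 20, B20 48, D20 34, E20 37), named by section and egg. Fewer libraries leave fewer degrees of freedom, which does not account for every shift. Without section A of egg 10 every total rose, also for pairs without section A. The F test then called 10227, E versus A 10514, B versus A 1385, C versus B 3271, D versus C 1044 and E versus D 218. Leaving out all of egg 10 also lowered the F test less, to 8171, than leaving out egg 18 or egg 20. The cause was not tested. Section C of egg 20 was the shallowest library. The gene lists and the removal of mitochondrial and ribosomal transcripts were not run, as no names were matched.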

Other observations

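The tests of evenness, of transcripts detected and of eggs in this part, and the removal of 2 transcripts, were chosen only after the data were examined. The vegetal sections held a less even mix of transcripts, which rested largely on the 2 most abundant. The effective number of transcripts, the exponential of the Shannon entropy of a library's counts, was 7957 ± 218 in section A, 8319 ± 421 in B, 7346 ± 712 in C, 6540 ± 1067 in D and 6260 ± 383 in E (SD, n = 3). The sections differed in a permutation test within eggs of any difference in level (p = 0.0047, 0.0093 after Benjamini-Hochberg adjustment over 4 measures), and E was below A in 3 of 3 eggs. The 100 most abundant transcripts of a library took 12.8 ± 0.702% of the counts in section A and 17.4 ± 0.933% in E, higher in E in 3 of 3 eggs (permutation p = 0.0069, 0.0093 adjusted). trinitytrinLocGG_75266c0g1t1 and trinitytrinLocGG_45939c0g1t1 together took 2.97 ± 0.297% of the counts in A and 6.76 ± 0.851% in E. Whether they are ribosomal or mitochondrial is not known, as no names were matched. Without them the effective number was 8952 ± 333 in A and 8620 ± 200 in E, and the 100 most abundant of the rest took 10.3 ± 0.896% and 11.5 ± 0.271%. E stayed below A in effective number in 3 of 3 eggs, but neither measure then passed the test (permutation p = 0.21 and 0.15, both 0.21 after Benjamini-Hochberg adjustment over 2 measures). At equal depth, the number of transcripts detected was 36206 ± 184 in A and 36045 ± 429 in E, and the sections did not pass that test (permutation p = 0.086, 0.086 adjusted).

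The eggs also differed from one another, in a comparison where each group is 1 egg and its 5 sections stand in for replicates. Its p-values therefore measure how evenly an egg differs over its sections, not the spread between eggs. Under the same edgeR model with Benjamini-Hochberg adjustment, 12286 transcripts differed between eggs, with 12438 between eggs 18 and 10, 6453 between eggs 20 and 10, and 3271 between eggs 20 and 18.

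For the F test, 9292 transcripts were called with the real sections, against at most 1701 in the 54 other orders of the sections drawn within eggs. Thus 1 of 55 orders gave a count as large, under the share of 0.05 set in advance and the smallest that these orders can give. The other orders leave the real section differences in the residual spread, which lowers their counts. The gap is therefore partly built in and does not exclude chance. For each pair of sections the 10 splits of 6 libraries are too few for a share under 0.05. The real count was 10222 for E versus A, 986 for B versus A, 2531 for C versus B and 732 for D versus C, where the highest of the other splits gave 0, and 82 for E versus D, where it gave 1. That split ignored the pairing by egg. Other splits that part the 2 libraries of each egg gave 0 in every comparison. These splits too leave the real section differences in the residual spread.

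Transcripts of 1 Trinity component, a group of related assembled sequences, lay alike along the axis. Of 310 components with 2 different genes past the test of E versus A, 81.0% had the same direction (95% exact binomial interval 76.1 to 85.2%), against 50% in random pairings, whose upper bound was 55.8%. A candidate explanation is that related sequences are placed together, and the value fits it. That value is the pattern itself, so it cannot test the explanation. Reads shared between near-identical sequences could give the same pattern: of 114 pairs changed at least 2-fold each, 9 or 7.89% lay in opposite directions (interval 3.67 to 14.5%). That share passes the bound of 5% set in advance against shared reads, but its interval holds the bound, a requirement added after the value was seen, so this explanation stays open.

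Genome-guided transcripts with consecutive numbers in their IDs also lay alike. Of 111 such pairs past the test of E versus A, 78.4% had the same direction, against 51.4% in random pairings with an upper bound of 60.4%. At a distance of 2 numbers the share was 68.6% of 70 pairs, and at a distance of 3 it was 58.1% of 74 pairs, within the random range. Consecutive numbers may mark pieces of 1 RNA or neighbouring loci, and which of these holds was not tested.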
